A study of Mus musculus with 18 samples.

How the data were processed

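Ovaries of 18 female Balb/c mice were profiled by 3' RNA sequencing, 1 library per mouse. The labels give 3 groups of 6 mice: young mice of 8 weeks given distilled water, aged mice of 40 weeks given distilled water, and aged mice of 40 weeks given Samul-tang, a herbal decoction, by mouth at 2.5 g/kg. Dosing took place 5 times a week for 4 weeks. Every mouse then received 5 IU of pregnant mare serum gonadotropin and, 48 hours later, 5 IU of human chorionic gonadotropin (hCG), and the ovaries were taken 16 hours after hCG, which the protocol describes as a post-ovulatory state. Per the labels' protocols, aged mice with and without Samul-tang were separated within the same cage. Which mice shared a cage is not given in the sources used here.

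Libraries were made with the QuantSeq 3' kit, per the labels' protocols, which reads the 3' end of each polyadenylated transcript, so that counts need no correction for transcript length. The submitters' processing notes name FastQC 1.9, STAR 2.7.9a, RSEM 1.3.3 and the build GRCm39. Per the file headers, the authors deposited 1 RSEM gene table per library with expected counts and TPM values for 55416 genes. RSEM shares reads that match several genes among them, so expected counts need not be whole; 87.4% of the deposited expected counts lay within 0.005 of a whole number, and 67.4% of those of the genes tested. TPM values were made by the authors with a division by effective gene length and scaled to 1000000 per library. That division does not suit 3' tags, so the deposited TPM values were used only as an alternative. The annotation and the strand setting of the counting are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies such as ribosomal protein, histone and histocompatibility genes, may therefore share reads. Gene symbols came from a mouse annotation of another build and were matched by Ensembl identifier; 52083 of 55416 identifiers had a symbol, and no coordinates were used. The gene with the most counts, ENSMUSG00000119584, had no symbol there and is given by its identifier.

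Expected counts were rounded to whole numbers. Totals per library, in units of 1000000, ran from 9.05 to 20.35, so that 1 CPM (1 count in 1000000) stood for 9 to 20 counts. Genes were kept by the edgeR filter for counts (at least 10 counts at the median depth in about the size of the smallest group, and at least 15 in all), which left 16959 genes. Counts were scaled by TMM, with factors from 0.94 to 1.07, and tested with the edgeR 4.0.16 quasi-likelihood test (robust dispersions, two-sided) in R 4.3.3. All 18 libraries entered 1 fit with 3 group means, and the 3 comparisons were contrasts within it. P-values were adjusted over all genes by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with the standard error (SE) of the fit; group levels are mean CPM ± SD with n = 6.

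There were 36 gene lists, for ovarian and other cell types, steroid and cholesterol metabolism, immunity, matrix, cell cycle, stress and signalling. Each was tested with camera of limma 3.58.1 on voom values of the same counts, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. A list needed at least 5 tested members. Camera with an estimated correlation and the directional test fry were alternatives. For each list the members past the edgeR threshold were counted, over all genes and adjusted over the list alone. 3 list members were matched through older symbols.

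Genes were named by a fixed rule. Part 1 took, in each comparison and direction, the 10 called genes with the largest fold change that had a mean of at least 5 CPM in the higher group and whose second lowest library of the higher group lay above the second highest of the lower group; predicted genes, pseudogenes and immunoglobulin or T cell receptor variable segments were counted but not named. Part 2 took up to 4 members with the smallest p of each list that passed its test or had a called member. Part 3 was a panel of 14 genes: Star, Cyp11a1, Hsd3b1, Cyp19a1, Cyp17a1, Lhcgr, Fshr, Amh, Gdf9, Bmp15, Zp3, Pgr, Adgre1 and Col1a1. Part 4 took up to 10 genes called in opposite directions with age and with Samul-tang. The text prints a part of the genes that the rule gives, and that part was picked after their values had been seen; some genes that the rule gives are not reported here. Groups, tests, gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

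Library measures were compared by two-sided exact permutation tests of the difference of means over all 924 regroupings of 12 libraries, which cannot give a p below 0.00216. Over 153 pairs of libraries, the lowest chi-square per degree of freedom of the counts was 4.11, so no pair agreed within sampling noise. Because the aged controls enter both the age and the Samul-tang comparison, the agreement of the 2 sets of fold changes was set beside 10 simulations without any effect, 10 simulations with an age effect alone, and all 10 divisions of the aged controls into 3 and 3 libraries, each taken both ways round.

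Alternatives were other scalings (RLE, upper quartile, TMM without the 10 most abundant genes), no filter on counts or a floor of 1 CPM in 6 libraries, a fit of only the 12 libraries compared, the replicate number as a block, DESeq2 1.42.0, voom with sample quality weights, limma on log2(TPM + 1) or, for single genes, log2(TPM + 0.1), 1 surrogate variable (sva 3.50.0), a floor of 1 on the absolute log2 fold change, and leaving out each library in turn. Added after seeing the data were a gene length trend removed from each library, the share of ENSMUSG00000119584 as a covariate, treated libraries thinned at random to the mean depth of the aged controls, and fits without treated libraries 1, 2 and 3 or without young control 3 and treated library 6. The code was tested on simulated data: for aged control against young control, 35 of 47 genes changed 2-fold and 46 of 48 changed 4-fold were recovered with 5 false calls among 115, and for Samul-tang against aged control, 32 of 50 and 49 of 50, with 4 false calls among 116. At a simulated change of 1.5-fold, 21 of 49 and 23 of 49 were recovered. Each of these 2 simulations tested 16678 genes. Figures were drawn with matplotlib 3.10.9.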

Results

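The data set described the ovarian transcriptome of young mice, aged mice and aged mice given Samul-tang, 6 mice per group, 16 hours after an ovulatory dose of hCG. The study's design asked how 4 weeks of Samul-tang changed the aged ovary, with young mice as the reference. Total expected counts per library, in units of 1000000, ran from 9.05 to 14.15 in young controls, from 11.61 to 13.43 in aged controls and from 14.2 to 20.35 in aged Samul-tang mice. The treated libraries were all deeper than the aged controls (17.24 ± 2.05 against 12.49 ± 0.72 in the same units, SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.00742). Whether they were prepared or sequenced apart from the other libraries is not stated in the sources used here, so such a batch could not be told apart from treatment. They also differed in composition. The most abundant gene, ENSMUSG00000119584, took 10.73 ± 3.13% of counts in treated and 15.45 ± 1.70% in untreated aged ovaries (exact permutation p = 0.00433, adjusted p = 0.013, n = 6). Ribosomal protein genes took 8.53 ± 0.32% against 7.50 ± 0.26% (exact permutation p = 0.00216, adjusted p = 0.00742, n = 6), and mitochondrial ribosomal RNA 1.64 ± 0.41% against 2.33 ± 0.20% (exact permutation p = 0.00866, adjusted p = 0.0173, n = 6). Adjustment here was over 24 tests of library measures. Between aged and young controls depth did not differ (exact permutation p = 0.965, n = 6), while fewer genes were detected in the aged ovaries (22850 ± 232 against 23680 ± 297; exact permutation p = 0.00216, adjusted p = 0.00742, n = 6).

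In aged against young control ovaries, most oocyte genes fell. Of 27 oocyte genes tested, 24 were called lower (26 adjusted over the list alone) and none higher, with a median log2 fold change of -1.69. Gdf9, an oocyte-secreted growth factor that acts on granulosa cells, fell from 30.9 ± 4.92 to 10.1 ± 2.58 CPM (SD, n = 6; log2 fold change -1.61 ± 0.17 SE, edgeR adjusted p = 1.44e-06). Bmp15, its close relative, changed by -1.89 ± 0.25, and the zona pellucida genes Zp2 and Zp3 by -1.94 ± 0.20 and -1.89 ± 0.23. Padi6, which is needed for early embryo development, changed by -1.46 ± 0.16. Of the 3 members not called, Tle6 and Gja4 stood at -0.27 ± 0.11 and -0.25 ± 0.18 and Oog1 at -1.78 ± 0.59; these 3 are named after their values were seen. The list passed camera (adjusted p = 1.26e-32) and kept its call with an estimated correlation (adjusted p = 0.0351). In all, 1912 of 16959 genes were called, 890 higher and 1022 lower, and 480 of them changed at least 2-fold, 118 higher and 362 lower.

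Most called genes of the granulosa, theca and interstitial, and smooth muscle and pericyte lists were lower as well. In the granulosa list 10 of 19 genes fell (14 adjusted over the list alone) and none rose (median -0.61; camera adjusted p = 2.26e-09, adjusted p = 0.144 with an estimated correlation). Esr2, the estrogen receptor of granulosa cells, went from 27.8 ± 7.44 to 7.74 ± 1.36 CPM (SD, n = 6; log2 -1.84 ± 0.18 SE), Slc18a2 changed by -1.86 ± 0.19 and the cyclin Ccnd2 by -0.54 ± 0.09. In the theca and interstitial list 6 of 15 genes fell and 2 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.118 with an estimated correlation). Insl3, a theca cell hormone, changed by -1.68 ± 0.17, and Ptch1 and Gli1, which respond to hedgehog signals, by -0.72 ± 0.08 and -1.04 ± 0.21. The theca list was no longer past the threshold in a fit of only the 12 libraries compared, or without young control 3 and treated library 6, the libraries with the lowest mean correlation with the others of their groups (0.964 and 0.963). In the smooth muscle and pericyte list 9 of 15 genes fell and none rose (9 and 2 adjusted over the list alone; camera adjusted p = 8.38e-06, adjusted p = 0.144 with an estimated correlation). Among them were the contractile genes Myh11 (-0.99 ± 0.10), Cnn1 (-0.92 ± 0.15) and Lmod1 (-0.91 ± 0.12).

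**Figure D1:**
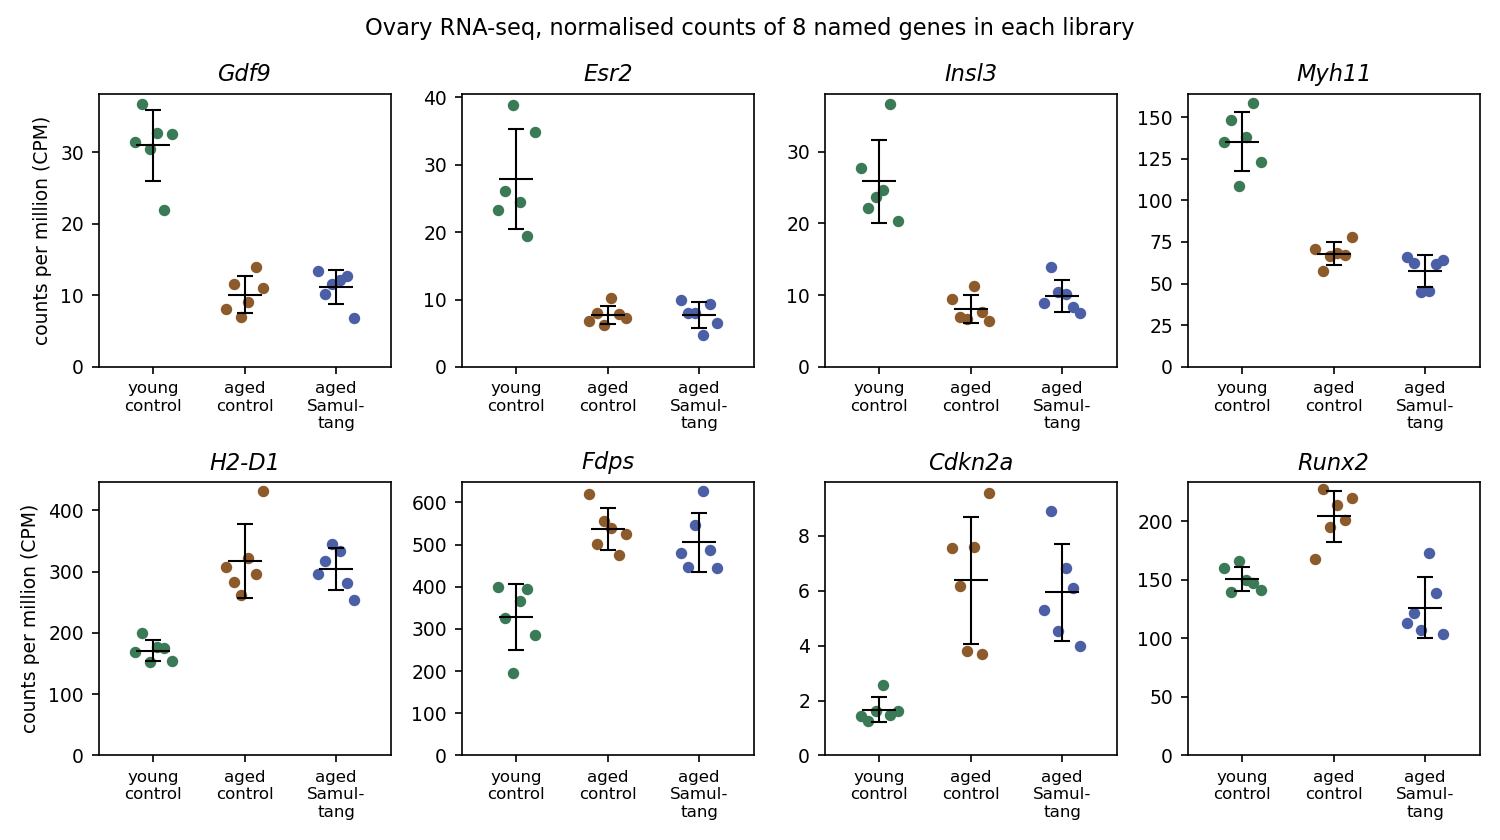
Normalised counts (CPM, linear axes from 0) of 8 named genes in each of the 18 libraries; points are mice and black bars the mean ± SD of 6. Gdf9, Esr2, Insl3 and Myh11 were lower and H2-D1, Fdps and Cdkn2a higher in both aged groups than in young controls, and Runx2 was 126 ± 26.1 CPM in treated against 204 ± 21.5 CPM in untreated aged ovaries.

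Proliferation and repair genes were slightly lower. With fry the cell cycle list did not pass (adjusted p = 0.139) and the DNA repair list did (adjusted p = 0.000865). In the cell cycle list 6 of 28 genes fell (6 adjusted over the list alone; median -0.24; camera adjusted p = 6.24e-05, adjusted p = 0.392 with an estimated correlation), among them Ccne2 (-0.75 ± 0.12) and the replication helicase gene Mcm2 (-0.57 ± 0.09). In the DNA repair list 3 of 25 fell (4 adjusted over the list alone; camera adjusted p = 0.00243, adjusted p = 0.118 with an estimated correlation), led by Brca2 (-0.65 ± 0.12). In the collagen and fibrosis list 5 of 25 genes fell, such as Fbn1 (-0.45 ± 0.08) and Col1a2 (-0.38 ± 0.08), and Timp3 rose (0.26 ± 0.07; adjusted p up to 0.0877 on the log2 TPM scales, where its call was lost), with 5 lower and 2 higher adjusted over the list alone. That list passed camera (adjusted p = 0.0209), with adjusted p = 0.477 under an estimated correlation and 0.158 with fry. It was no longer past the threshold without any one of aged controls 2 and 6 and young controls 2, 4 and 5, with a gene length trend removed, or with the share of ENSMUSG00000119584 as a covariate. Its median ran from -0.24 to -0.14. In the stromal fibroblast list 5 of 16 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.176 with an estimated correlation), with the proteoglycan gene Ogn at -0.98 ± 0.09.

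Antigen presentation and interferon genes were higher in aged ovaries. In the MHC and antigen presentation list 11 of 14 genes rose (12 adjusted over the list alone; median 0.73; camera adjusted p = 1.3e-12, adjusted p = 0.0531 with an estimated correlation). The class I genes H2-D1 and H2-K1 rose by 0.89 ± 0.10 and 0.69 ± 0.10, the immunoproteasome gene Psmb9 by 0.77 ± 0.12 and H2-DMb1, which loads class II molecules, by 1.46 ± 0.25. Of 20 interferon-stimulated genes 6 rose (14 adjusted over the list alone; camera adjusted p = 9.69e-08, adjusted p = 0.144 with an estimated correlation), such as Rsad2 (1.49 ± 0.21) and Xaf1 (0.81 ± 0.11). In the macrophage list 3 of 20 rose (3 adjusted over the list alone; camera adjusted p = 0.0229, adjusted p = 0.477 with an estimated correlation). Gpnmb, a lysosomal glycoprotein gene of lipid-laden macrophages, went from 6.4 ± 4.84 to 40.5 ± 17.2 CPM (SD, n = 6; log2 2.71 ± 0.56 SE, edgeR adjusted p = 0.0049). Ctss changed by 0.85 ± 0.26 and C1qa by 0.32 ± 0.10, while the pan-macrophage gene Adgre1 did not pass (-0.28 ± 0.22). Ctss was past the threshold in 11 of 26 alternatives and C1qa in 13 of 26 (adjusted p up to 0.0955 and 0.124). Ctss lost its call without any one of aged controls 1, 2, 4, 5 and 6 and young controls 1, 2, 4, 5 and 6, and C1qa without any one of aged controls 1, 3, 4 and 6 and young controls 1, 2, 4, 5 and 6. The macrophage list was no longer past the threshold without any one of aged control 1, aged control 6 and young control 5, without treated libraries 1, 2 and 3, or with the share of ENSMUSG00000119584 as a covariate. With fry it did not pass either (adjusted p = 0.163). Its median ran from 0.07 to 0.30 over the alternatives.

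Steroid and lipid metabolism genes were modestly higher. All 24 genes for cholesterol synthesis and uptake had positive fold changes and 7 rose (13 adjusted over the list alone; camera adjusted p = 1.26e-08, adjusted p = 0.214 with an estimated correlation). They included the cholesterol synthesis genes Fdps (0.71 ± 0.14) and Sc5d (0.53 ± 0.12). In the luteal and steroidogenic list 2 of 21 rose, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000333, adjusted p = 0.118 with an estimated correlation). These were Cyp11a1, which makes pregnenolone from cholesterol (0.45 ± 0.08), and Hsd3b1, which makes progesterone from it (0.38 ± 0.07). Star, Lhcgr and Cyp19a1 did not pass (0.18 ± 0.21, 0.27 ± 0.30 and 0.62 ± 0.73). Fshr (-0.80 ± 0.28), Pgr (-0.70 ± 0.32) and Col1a1 (-0.27 ± 0.11) did not pass either. Lhcgr and Col1a1 were past the threshold in 1 of 26 alternatives each and Fshr in 4 of 26. The log2 fold change of Lhcgr ran from 0.17 to 0.53 over them. Cyp17a1, the androgen-making enzyme gene of theca cells, missed the threshold with a wide error (-2.35 ± 0.76, edgeR adjusted p = 0.059). Young control 3 had 383 CPM of it and the other young libraries 39.8 to 128 CPM, and without that library the log2 fold change was -1.44. Amh had 0 to 3 counts per library and was not tested. In the lipid droplet and fatty acid oxidation list 4 of 24 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00053, adjusted p = 0.0351 with an estimated correlation). Dgat1 rose by 0.85 ± 0.12 and Cpt1a by 0.40 ± 0.07, while the cholesterol exporter gene Abca1 changed by -1.20 ± 0.29.

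Smaller shifts ran through mitochondrial and stress genes. Nuclear oxidative phosphorylation genes rose in 10 of 29 cases (19 adjusted over the list alone; camera adjusted p = 1.09e-10, adjusted p = 0.118 with an estimated correlation), such as Sdhb (0.36 ± 0.06). Antioxidant genes rose in 4 of 26 cases (9 adjusted over the list alone; camera adjusted p = 0.000168, adjusted p = 0.0531 with an estimated correlation), such as Sod2 (0.38 ± 0.06) and Gpx1 (0.36 ± 0.08). Heat shock and unfolded protein genes rose in 4 of 22 cases (8 adjusted over the list alone; camera adjusted p = 0.00243, adjusted p = 0.392 with an estimated correlation), led by Herpud1 (0.70 ± 0.10) and Xbp1 (0.51 ± 0.09). With fry that list did not pass (adjusted p = 0.109). Ribosomal protein genes passed camera (adjusted p = 7.83e-07, adjusted p = 0.387 with an estimated correlation) with a median of only 0.08 and 2 of 44 genes called (1 adjusted over the list alone).

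**Figure D2:**
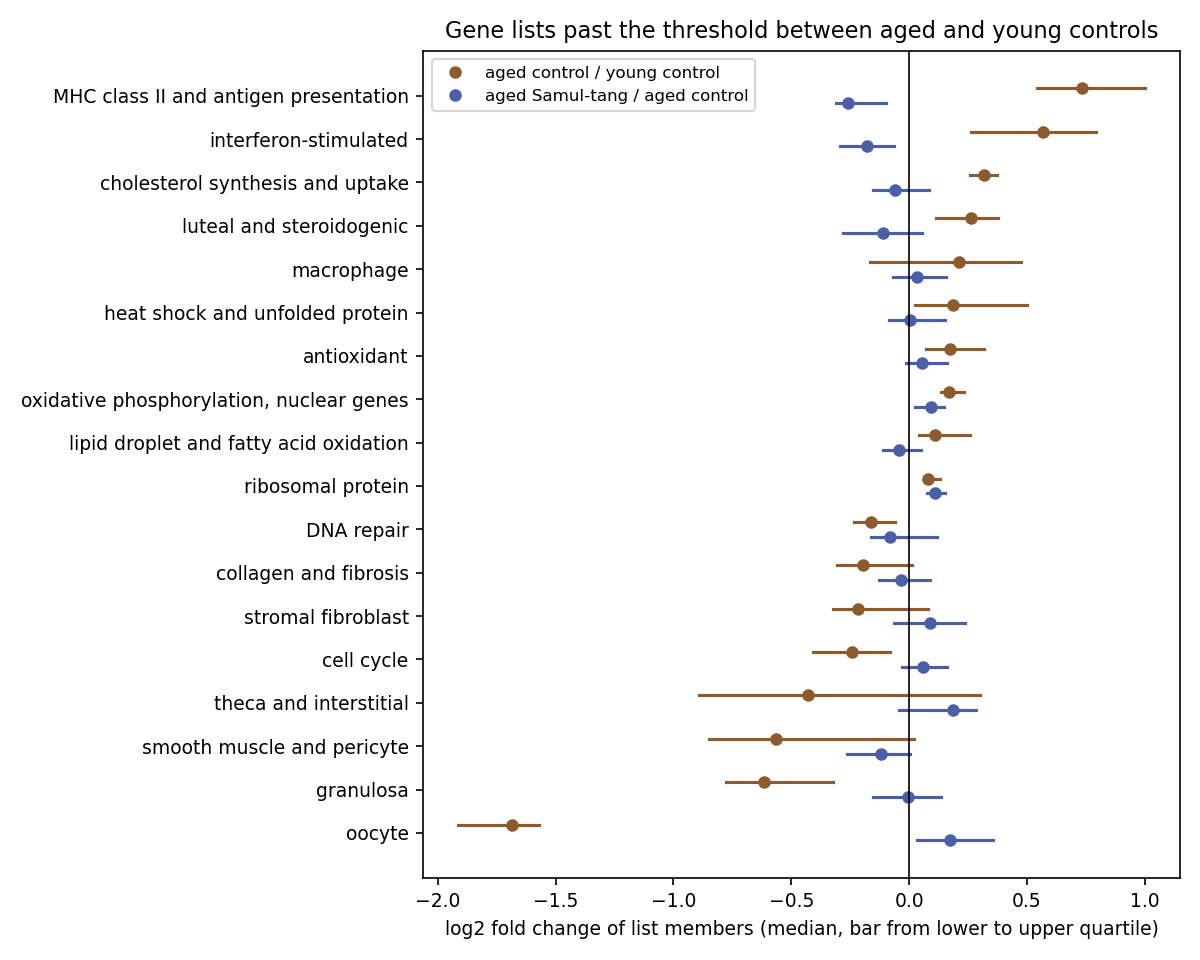
Median log2 fold change of the members of each of the 18 gene lists past the threshold between aged and young controls, with bars from the lower to the upper quartile of members; brown is aged control against young control and blue aged Samul-tang against aged control. Oocyte genes had a median of -1.69 with age and 0.17 with Samul-tang, and the antigen presentation list 0.73 and -0.26.

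The other 18 lists did not pass between aged and young controls, although single members did. In the senescence and inflammaging list (camera adjusted p = 0.39) 3 of 20 genes rose and 1 fell (4 and 2 adjusted over the list alone). Cdkn2a, which encodes the cell cycle inhibitor p16, was one of the 10 genes with the largest rise by the naming rule. It went from 1.66 ± 0.46 to 6.39 ± 2.32 CPM (SD, n = 6, log2 1.94 ± 0.26 SE, edgeR adjusted p = 1.79e-05). Igfbp5 fell (-0.94 ± 0.11). In the complement list 4 of 13 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0748), with C3 at 1.02 ± 0.24 and C1s1 at 0.64 ± 0.09. The B and plasma cell list had 4 of 9 higher and 1 lower (camera adjusted p = 0.149): the antibody genes Igkc and Jchain rose by 1.81 ± 0.47 and 1.45 ± 0.38, while Derl3 changed by -1.70 ± 0.19. The T and NK cell list had 1 of 9 higher, Trbc2 at 1.34 ± 0.28 (camera adjusted p = 0.0565). Endothelial genes went both ways, 4 of 20 higher and 3 lower (camera adjusted p = 0.0781), with Plvap at 1.02 ± 0.21 and the lymphatic gene Lyve1 at -0.80 ± 0.21. The Wnt pathway list had 4 of 41 genes higher and 6 lower (camera adjusted p = 0.954), with Wnt4 (0.85 ± 0.18) and the receptor gene Fzd4 (0.37 ± 0.08) among those higher and the inhibitor gene Dkk3 (-0.48 ± 0.10) among those lower. In the PI3K, AKT and FOXO list 2 of 29 rose and 2 fell (camera adjusted p = 0.56), including Foxo1 (-0.80 ± 0.13). The TGF-beta and BMP list had 4 of 30 lower (camera adjusted p = 0.0565), led by the BMP receptor gene Bmpr1b (-1.57 ± 0.28).

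Few members were called in the lists that remain. The camera adjusted p was 0.245 for ovulation and cumulus expansion (1 of 20 higher, Runx2), 0.314 for adipocyte (2 of 9 higher, among them Fabp4) and 0.321 for oviduct epithelium genes (1 of 7 lower). It was 0.132 for ovarian surface epithelium and mesothelium (2 of 15 higher and 2 lower), 0.0565 for erythrocyte (1 of 6 lower) and 0.0971 for mitochondrial genome genes (1 of 15 higher). For the last lists it was 0.959 for immediate early genes (1 of 23 higher and 1 lower), 0.924 for apoptosis (1 of 22 lower), 0.981 for neutrophil (0 of 5) and 0.847 for mast cell (0 of 6). Further large rises by the naming rule were those of Cpxm2 (2.55 ± 0.40), the neuropeptide gene Adcyap1 (2.51 ± 0.45), Adh6b (2.27 ± 0.33), Mal (2.07 ± 0.22), Tmem178 (1.87 ± 0.27) and Sectm1a (1.86 ± 0.14), beside that of the lipid-binding protein gene Fabp4 (2.65 ± 0.33). The largest falls by the naming rule included the apolipoprotein genes Apoa4 (-2.56 ± 0.39) and Apoa1 (-2.05 ± 0.26) and Sv2c (-2.29 ± 0.63). Among them too were Rfpl4 (-2.28 ± 0.33), Trim61 (-2.23 ± 0.25) and the retinoic acid binding protein gene Crabp2 (-2.22 ± 0.22). Sel1l3 (-2.21 ± 0.24), Cnmd (-2.20 ± 0.31), Car14 (-2.13 ± 0.43) and Dppa5a (-2.03 ± 0.29) completed them. Sv2c was past the threshold in 17 of 26 alternatives (adjusted p up to 0.0842), and lost its call without any one of aged controls 2, 4, 5 and 6 and young controls 4 and 5. Of the 1912 called genes, 167 were predicted, unnamed or variable segments.

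Aged Samul-tang ovaries differed from aged control ovaries in 176 of 16959 genes, 93 higher and 83 lower, and 12 of these changed at least 2-fold. Runx2, a transcription factor gene induced in ovulating follicles, fell from 204 ± 21.5 to 126 ± 26.1 CPM (SD, n = 6; log2 -0.69 ± 0.10 SE, edgeR adjusted p = 0.00406), after rising by 0.44 ± 0.10 with age. The largest rises by the naming rule were those of the growth factor receptor gene Fgfr2 (33.1 ± 8.77 against 21.0 ± 4.05 CPM, SD, n = 6; 0.66 ± 0.15, edgeR adjusted p = 0.0354) and the folate hydrolase gene Ggh (0.58 ± 0.11). Next came Rpl37rt (0.51 ± 0.09), Surf2 (0.47 ± 0.08), Pptc7 (0.47 ± 0.11), Ngly1 (0.47 ± 0.09). Others were the growth factor gene Pdgfd (0.46 ± 0.10), Selenof (0.46 ± 0.09), the mitochondrial pyruvate carrier gene Mpc1 (0.46 ± 0.09) and Ptpn23 (0.45 ± 0.11). The largest falls by the naming rule were led by the histone gene Hist2h2aa1 (-1.08 ± 0.22), the kinase gene Rps6ka2 (-0.94 ± 0.19) and Cog1 (-0.89 ± 0.16). Lrrtm2 (-0.83 ± 0.19) and Nlrx1 (-0.81 ± 0.16) came next. Smaller falls were those of Pclo (-0.77 ± 0.19), Runx2, Zfhx4 (-0.59 ± 0.14), Cep131 (-0.56 ± 0.14) and Plekha5 (-0.55 ± 0.12). Genes called higher had a median length of 1168 bases in the deposited tables and those called lower 3612, against 2194 for all genes tested.

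None of the follicle, oocyte or steroid genes of the panel passed the threshold with Samul-tang. Gdf9 was 11.1 ± 2.35 against 10.1 ± 2.58 CPM (SD, n = 6; 0.14 ± 0.17 SE), and Bmp15 and Zp3 had 0.10 ± 0.26 and 0.35 ± 0.23. Hsd3b1 came closest (0.22 ± 0.07, edgeR adjusted p = 0.089). Cyp11a1 stood at 0.10 ± 0.08, Star at 0.10 ± 0.21 and Lhcgr at -0.52 ± 0.30. Cyp17a1 stood at 0.71 ± 0.74, Cyp19a1 at -0.02 ± 0.70, Fshr at -0.01 ± 0.28, Pgr at 0.44 ± 0.31, Adgre1 at 0.10 ± 0.21 and Col1a1 at 0.08 ± 0.11. No member was called in the lists for oocyte (0 of 27), granulosa (0 of 19), luteal and steroidogenic (0 of 21), theca and interstitial (0 of 15) or Wnt pathway genes (0 of 41). Their camera adjusted p was 0.39, 0.823, 0.124, 0.58 and 0.39. Fold changes were positive in 21 of 27, 9 of 19, 7 of 21, 10 of 15 and 18 of 41 members, in that order. Over all genes tested 1.04% were called, so the absence of calls in lists of these sizes says little.

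The ribosomal protein list was higher with Samul-tang, with positive fold changes in 42 of 44 genes, a median of 0.11 and 3 genes called (7 adjusted over the list alone; camera adjusted p = 3.61e-11, adjusted p = 0.756 with an estimated correlation). Rps2 changed by 0.33 ± 0.07, Rpl32 by 0.25 ± 0.06 and Rpl5 by 0.25 ± 0.06. Nuclear oxidative phosphorylation genes followed, 25 of 29 with positive fold changes and Uqcrc2 called at 0.29 ± 0.06 (3 adjusted over the list alone; camera adjusted p = 0.000225, adjusted p = 0.774 with an estimated correlation). This list lost its call when a gene length trend was removed or when the share of ENSMUSG00000119584 entered as a covariate, where its median was -0.01. All 14 antigen presentation genes had negative fold changes and none was called (1 adjusted over the list alone; median -0.26; camera adjusted p = 0.0474, adjusted p = 0.774 with an estimated correlation); H2-K1 stood at -0.35 ± 0.10 (edgeR adjusted p = 0.0796). That list missed the threshold without any one of aged controls 4 and 6 (median -0.02 without aged control 6) and treated libraries 5 and 6, without young control 3 and treated library 6 together, without a filter on low counts, on log2(TPM + 1), and with the share of ENSMUSG00000119584 as a covariate, where its median was 0.04. Single genes called in lists that did not pass were Runx2 of the ovulation list, Pcna of the cell cycle list (0.33 ± 0.07), Txnrd1 of the antioxidant list (-0.36 ± 0.07), Igf1r of the PI3K, AKT and FOXO list (-0.32 ± 0.07) and mt-Nd5 of the mitochondrial genome list (-0.25 ± 0.06). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 did not pass (-0.75 ± 0.20 and -0.49 ± 0.13). Each was past the threshold in 5 of 26 alternatives. Over these mt-Rnr1 ran from -0.91 to -0.14 and mt-Rnr2 from -0.58 to -0.06. In the ovulation and cumulus expansion list Ereg stood at 1.54 ± 0.69, with 36.5 CPM in treated library 6 and 2.79 to 5.71 CPM in the other treated libraries; without that library it was 0.21.

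The number of Samul-tang calls rested on which libraries entered. It was 99 without aged control 1, 102 without aged control 2, 78 without aged control 3, 72 without aged control 4 and 85 without aged control 6. It was 60 without treated library 1, 105 without treated library 2, 32 without treated library 3, 593 without treated library 4 and 318 without treated library 5. It was 10 without treated libraries 1, 2 and 3 together, in which ENSMUSG00000119584 took 6.20 to 10.2% of counts, and 0 with that share as a covariate (edgeR; 2861 genes had an unadjusted p under 0.05 without the covariate, and DESeq2 without it called 663). Of the 37 called genes named here, 0 stayed past the threshold in all alternatives run for single genes, and all 37 kept their sign. That 0 was fixed by the covariate fit, which called no gene. Single genes were past the threshold in 10 of 26 alternatives (Pclo) up to 25 of 26 (Rpl37rt).

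A score of the called genes, the mean log2 CPM of those higher minus that of those lower, was 0.33 ± 0.22 in treated and -0.65 ± 0.04 in untreated aged libraries (SD, n = 6). Over the 12 control libraries, centred within group, it fell with the share of ENSMUSG00000119584 (Pearson r = -0.59, permutation p = 0.0216, adjusted p = 0.0319; Spearman rho = -0.73, permutation p = 0.0126; r = -0.58 without the 2 libraries farthest from the median share). Within the 6 treated libraries r was -0.85 (exact permutation p = 0.0319, adjusted p = 0.0319), rho was -0.83 (exact permutation p = 0.0583), and r was -0.61 without the 2 farthest libraries. These were 2 relations. The genes of the score were called between treated and untreated aged libraries. The gap between these groups was thus fixed by that choice and is no separate evidence of a difference. Both relations also include libraries that were used to pick the genes.

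**Figure D3:**
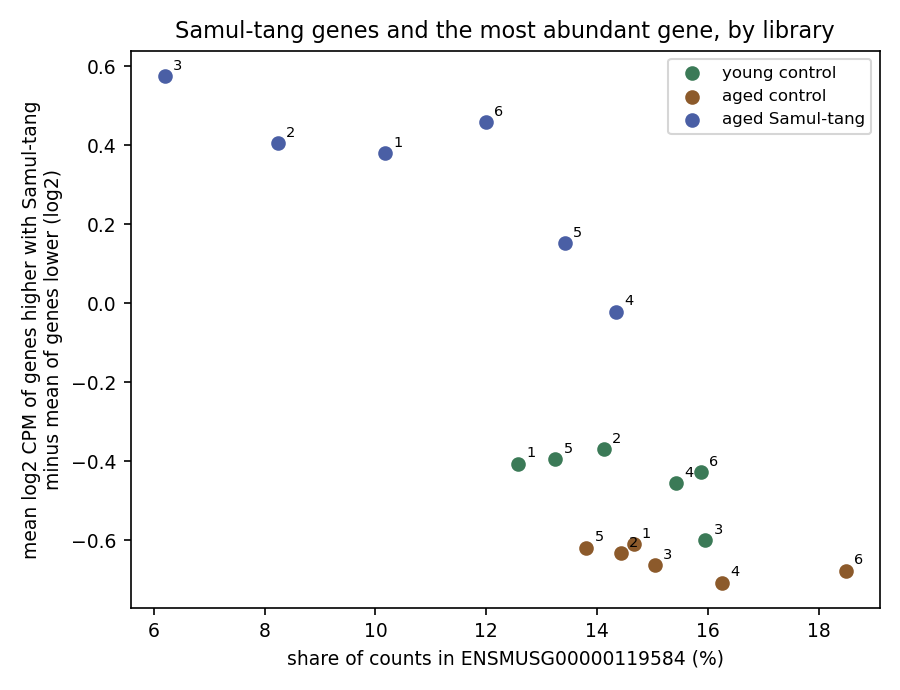
Score of the genes called between treated and untreated aged ovaries (vertical axis, log2 CPM) against the percent of counts taken by ENSMUSG00000119584 (horizontal axis) in the 18 libraries, coloured by group. Treated libraries averaged 10.7% and a score of 0.33, and aged controls 15.4% and -0.65. The genes were called between these groups, so the gap in score between them was fixed by that choice.

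Of the 1912 genes changed with age, 17 were also called in the opposite direction with Samul-tang and 4 in the same direction. Independent lists of these sizes would share 9.96 and 9.88 genes. That figure leaves out the shared aged controls; simulations with an age effect alone gave 0.3 and 0 genes on average, from 0.3 genes called with treatment, and divided controls 0.15 and 0.05, from 6.35. Of the 17, 9 were higher with age and lower with treatment and 8 the reverse. They included Runx2, Aplp2 (-0.53 ± 0.12 with treatment), Abca2 (-0.39 ± 0.09) and the matrix gene Aebp1 (-0.38 ± 0.09). In the other direction they included Hs6st2 (0.43 ± 0.10), Slc25a22 (0.45 ± 0.11), Ptpro (1.94 ± 0.40, at under 1 CPM in both groups) and the predicted genes Gm3636 (2.65 ± 0.55, and 3.41 without aged control 6) and Gm37214 (0.83 ± 0.20). Among all age-changed genes 61.2% had a Samul-tang fold change of the opposite sign. Both comparisons used the same aged controls, and simulations with an age effect and no treatment effect gave 58.7% (57.1 to 61.7%). The slope of the Samul-tang on the age fold changes over these genes was -0.122, steeper than in those simulations (-0.0615 on average, -0.0819 to -0.053) and than with divided controls (-0.0324, -0.0925 to 0.0182). With the aged controls divided between the comparisons the share was 52.3% on average (43.4 to 58.2%). Across genes, which are not independent replicates, the Pearson correlation of the fold changes was -0.288, against -0.522 in simulations without any effect, -0.328 (-0.375 to -0.299) with an age effect alone and -0.058 with divided controls. The covariance was -0.0378, against -0.0366 without any effect and -0.0355 with an age effect alone.

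Aged Samul-tang ovaries differed from young control ovaries in 3795 genes, 1954 higher and 1841 lower, and 585 of these changed at least 2-fold. Oocyte genes were lower here too, 26 of 27 (26 adjusted over the list alone; median -1.58; camera adjusted p = 3.28e-23, adjusted p = 0.081 with an estimated correlation). Gdf9 stood at -1.47 ± 0.16, Bmp15 at -1.79 ± 0.24, Zp3 at -1.53 ± 0.22, Nlrp14 at -1.84 ± 0.18 and the germ cell RNA-binding gene Ybx2 at -2.10 ± 0.23. Granulosa genes fell in 10 of 19 cases (12 adjusted over the list alone; camera adjusted p = 1.51e-07, adjusted p = 0.204 with an estimated correlation), including Esr2 (-1.83 ± 0.18). Smooth muscle and pericyte genes fell in 10 of 15 cases (10 adjusted over the list alone; camera adjusted p = 4.95e-06, adjusted p = 0.189 with an estimated correlation), including Myh11 (-1.24 ± 0.10) and Lmod1 (-1.27 ± 0.12). Insl3 (-1.39 ± 0.16) and Ptch1 (-0.78 ± 0.08) were lower and Cyp11a1 (0.55 ± 0.08) and Hsd3b1 (0.60 ± 0.07) higher. Fshr (-0.80 ± 0.27) was past the threshold in 14 of 26 alternatives (adjusted p up to 0.497), and lost its call without any one of young controls 3 and 6 and treated libraries 3, 4, 5 and 6. Star (0.28 ± 0.21), Cyp19a1 (0.60 ± 0.72), Cyp17a1 (-1.64 ± 0.73), Lhcgr (-0.25 ± 0.30), Pgr (-0.26 ± 0.30), Adgre1 (-0.18 ± 0.21) and Col1a1 (-0.19 ± 0.11) did not pass. Without young control 3, which had 383 CPM of Cyp17a1, that gene stood at -0.73.

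Ribosomal protein and respiratory chain genes were higher. Of 44 ribosomal protein genes 33 rose (39 adjusted over the list alone; median 0.21; camera adjusted p = 1.97e-16, adjusted p = 0.189 with an estimated correlation), with Rps2 at 0.49 ± 0.07 and Rpsa at 0.35 ± 0.05. Of 29 nuclear oxidative phosphorylation genes 23 rose (25 adjusted over the list alone; camera adjusted p = 8.97e-15, adjusted p = 0.081 with an estimated correlation), with Sdhb at 0.48 ± 0.06. The treated libraries also held a higher share of ribosomal protein counts than the young ones (8.53 ± 0.32 against 7.35 ± 0.34%; exact permutation p = 0.00216, adjusted p = 0.00742, n = 6). Antigen presentation genes rose in 9 of 14 cases (11 adjusted over the list alone; camera adjusted p = 3.51e-06, adjusted p = 0.192 with an estimated correlation), with H2-D1 at 0.83 ± 0.10. Complement genes rose in 5 of 13 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.081 with an estimated correlation), with C3 at 1.40 ± 0.24. In all 18 lists passed, 11 higher and 7 lower, and none kept its call with an estimated correlation. The largest rises by the naming rule were led by Adcyap1 (3.30 ± 0.45), Fabp4 (2.80 ± 0.33) and Gpnmb (2.74 ± 0.56). Cpxm2 (2.49 ± 0.40), Mal (2.23 ± 0.22) and Sectm1a (2.06 ± 0.14) followed. Behind them came Lix1 (1.95 ± 0.16), the alarmin gene Il33 (1.93 ± 0.22), Rpgrip1 (1.93 ± 0.51) and Adh7 (1.88 ± 0.33). The largest falls by the naming rule were led by Car14 (-2.83 ± 0.44), Apoa4 (-2.31 ± 0.38), Ybx2 and Sv2c (-2.04 ± 0.60). Ccno (-1.92 ± 0.27), Slc38a5 (-1.86 ± 0.30), Nlrp14, Esr2, Oas1e (-1.83 ± 0.24) and Cnmd (-1.83 ± 0.29) followed. Sv2c was past the threshold in 19 of 26 alternatives (adjusted p up to 0.202), and lost its call without any one of young control 4 and treated libraries 1 and 2; without young control 3 and treated library 6 it was -2.97. Rpgrip1 lost its call with the share of ENSMUSG00000119584 as a covariate (adjusted p = 0.192) and without treated libraries 1, 2 and 3. The count of 3795 called genes fell to 1367 with the share of ENSMUSG00000119584 as a covariate and to 1851 without treated libraries 1, 2 and 3.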

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

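The tests of the composition share as the whole cause, of the shared aged controls, and of composition in the comparison with young ovaries were chosen after the results they bear on had been seen; all 3 had their criteria changed after a first version came out. Single libraries stood apart from the other 5 of their group in 21 of 325 groups of values (6.46%, where chance gives about 5%), by the gap of the farthest library relative to the range.

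Young control 3 stood apart in 6 of these. It had the lowest Star (697 CPM, others 1380 to 1800), H2-K1 (44.3, others 61.4 to 68.2), Fbn1 (46.3, others 51.2 to 53.9), Dgat1 (24.9, others 37.7 to 46.9) and Adcyap1 (0.32, others 2.95 to 6.88) and the highest Lhcgr (414, others 164 to 232). Aged Samul-tang 6 stood apart in 6. It had the lowest Cpxm2 (5.66 CPM, others 24.0 to 35.5), Lhcgr (62.9, others 182 to 257) and Gm19391 (1.60, others 2.08 to 2.32) and the highest C3 (73.1, others 28.0 to 35.3), Hs6st2 (46.7, others 36.5 to 37.9) and Ereg (36.5, others 2.79 to 5.71). No explanation was tested for either library.

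Aged control 5 had the lowest Adgre1 (1.69 CPM, others 3.44 to 4.11) and the highest Mcm2 (19.1, others 15.3 to 16.6) and Pcna (58.1, others 50.8 to 52.8). Fabp4 was highest in aged control 1 (63.5 CPM, others 29.3 to 38.6) and Cdkn2a in young control 4 (2.56, others 1.26 to 1.63). Gdf9 was lowest in young control 5 (21.9 CPM, others 30.5 to 36.7), and Gli1 in aged control 2 (3.17, others 4.67 to 5.80). Pgr was highest in aged Samul-tang 1 (3.79 CPM, others 1.22 to 1.85). The ribosomal protein share was lowest in aged Samul-tang 4 (7.93%, others 8.50 to 8.82%).

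In treated against untreated aged ovaries, genes called higher were short and genes called lower long. The other comparisons had the same order of median lengths. With age they were 1975 bases for higher and 2501 for lower genes, and for treated against young 1651 and 2683. The rank correlation of expression with length per library also differed between aged and young controls (-0.001 ± 0.048 against 0.062 ± 0.036, exact permutation p = 0.0152, adjusted p = 0.028, n = 6). Removing a length trend from each library left a median of 0.94 of the log2 fold changes of the 176 genes called with Samul-tang (quartiles 0.89 to 1.00). That argues against such a trend as the cause for these 176 genes. Thinning the treated libraries to the aged control depth left 1.00 (0.98 to 1.02). Random thinning keeps the expected share of each gene, so this ratio could hardly differ and cannot decide on depth. Library composition may contribute: over the 12 control libraries the score of the called genes fell with the share of ENSMUSG00000119584 (r = -0.59). Whether that share is the whole cause cannot be told apart from treatment: the slope within control libraries gives 11.7% of the score difference (95% confidence interval -0.2 to 23.7%), but 4 of 6 treated libraries lie outside the shares of the controls and the score rests on genes chosen for that difference. The other 2, aged Samul-tang 4 and 5, scored -0.021 and 0.153 on those genes, above all aged controls (-0.707 to -0.61). On genes picked without them and without 3 of the aged controls, they lay above the 95% prediction interval of the line through the controls not used for the picking in 42.5% of 40 cases, aged Samul-tang 4 in 2 of 20 and aged Samul-tang 5 in 15 of 20 (median excess 0.11 and 0.26). Their distance on the called genes thus depends on the choice of genes, and 1 library does not decide. With the share as a covariate a median of 0.74 of the fold change was left (quartiles 0.56 to 0.91) while the median SE went from 0.083 to 0.105, and no gene was called; a treatment effect on the ovary stays open, as the share differs with treatment.

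Of the genes changed with age, 61.2% had a treatment fold change of the opposite sign, that is, towards the young level. This lies within the 57.1 to 61.7% that simulations with an age effect and no treatment effect gave through the shared aged controls, which may account for it. By the criterion first written, the share alone, that would do. The slope of the treatment on the age fold changes over these genes was added after that result. It was -0.122, outside the -0.0819 to -0.053 of those simulations. The covariance of -0.0378 lay within their -0.0429 to -0.0312. The Pearson correlation of -0.288 was weaker than their -0.375 to -0.299. Those simulations called 1357 to 1412 genes with age, against 1912 in the data. As the measures differ, shared controls and a treatment effect cannot be told apart here. With divided controls, no aged control entered both comparisons. The share was then 52.3% (43.4 to 58.2%), the slope -0.0324 (-0.0925 to 0.0182) and the covariance -0.01 (-0.0188 to 0.00214). Each range over the divisions included the value expected without a shift. The divisions reuse the same libraries, so these ranges are not confidence intervals and cannot decide whether there was a shift. The covariance was above 0 only with aged controls 1, 2 and 3 in the age comparison (0.00214).

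More genes were called against young ovaries in treated (3795) than in untreated aged ovaries (1912), a ratio of 1.98. The ratio was 1.95 with treated libraries thinned and 1.93 with the length trend removed. The second value argues against a length trend. The first argues only against the number of reads as such, with a median SE of 0.102 before and 0.103 after thinning. Thinning keeps the expected share of each gene, so it cannot decide on other differences that go with depth. The ratio was not kept throughout: 0.72 with 1 surrogate variable (1611 against 2233), 0.90 without treated libraries 1, 2 and 3 (1851 against 2067), 1.22 for changes of at least 2-fold, 1.44 with only the 12 libraries compared (3313 against 2307) and 1.45 with voom weights (4012 against 2767). With the share of ENSMUSG00000119584 as a covariate it was 0.60 (1367 against 2293), but a median of 0.84 of the log2 fold changes was left (lower quartile 0.64) with a larger SE. By the criterion first written, the fold changes alone, that argued against composition; with the count added, as it was after that result, composition and treatment cannot be told apart, since the share differs between the groups.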

How the results depend on the processing

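Fits with a length trend removed, the share of ENSMUSG00000119584 as a covariate, treated libraries thinned, or libraries left out together were chosen after seeing the data. Single named genes were checked in up to 26 alternatives, without voom weights, the surrogate variable, the 1 CPM floor or the fold change floor. Of those past the threshold, 73 of 77 with age and 32 of 35 for treated against young stayed past it in all of these. With Samul-tang 0 of 37 did, which was fixed because the covariate fit called no gene there. All kept their sign. The 1912 age calls ran from 1505 to 1805 with 1 library left out, and the 3795 calls of treated against young from 3090 to 3920. On log2(TPM + 1) 33.6% of age calls were higher against 46.5%, and 40.4% against 51.5% for treated against young. With an absolute log2 fold change of at least 1, calls fell to 480, 12 and 585, as the stricter criterion requires.

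Samul-tang calls were 45 with only the 12 libraries compared, 663 with DESeq2, 293 with voom weights, 2 with 1 surrogate variable, 0 with the covariate, 10 without treated libraries 1, 2 and 3 and 483 without young control 3 and treated library 6, against 176. Leaving out 1 library gave 32 to 593. Calls of treated against young were 1611 with 1 surrogate variable, 1367 with the covariate and 1851 without treated libraries 1, 2 and 3. Apart from the smaller groups, the cause was not tested.

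Lists past the threshold with an estimated correlation were 2, 0 and 0, against 18, 3 and 18. With fry they were 17, 0 and 16. With Samul-tang they were 8 without a filter, 0 with fry (lowest adjusted p 0.101; 0.744 with an estimated correlation), 5 with the covariate and 10 without treated libraries 1, 2 and 3; leaving out 1 library gave 2 to 7 (5 without aged control 3, 6 without treated library 1, 7 without treated library 2). Leaving out 1 library gave 16 to 23 lists with age and 12 to 19 for treated against young. With Samul-tang the oxidative phosphorylation median reversed to -0.008 with the covariate, and the cell cycle median to -0.22 without treated libraries 1, 2 and 3. The antigen presentation median also changed sign with the covariate. The cause was not tested.

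The 61.2% of age-changed genes with the opposite sign was 52.3% with divided controls, 71.0% at an absolute log2 fold change of at least 1 and 68.4% with the covariate, and 59.8 to 67.7% with 1 library left out. The 17 genes called in opposite directions were 0.15 on average with divided controls, 3 at that fold change, 70 with DESeq2, 0 with the covariate, 1 without treated libraries 1, 2 and 3 and 48 without young control 3 and treated library 6, and 3 to 60 with 1 library left out. The correlation of -0.288 was -0.058 with divided controls, -0.23 as Spearman's rho and -0.359 with the covariate, and -0.393 to -0.252 with 1 library left out. The cause was not tested.

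With the replicate number as a block, calls were 1756, 139 and 3535, lists 23, 3 and 19, and the 3 values on age-changed genes 62.2%, 15 and -0.274. Deviations of same-numbered libraries correlated from -0.118 to 0.074, so expression gave no sign that the numbers pair the mice. Self-tests recovered 8 of 50 genes at the smallest simulated change, so small changes were mostly missed at this depth and n.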

Other observations

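The test of the oocyte hypothesis was first written for the called members alone and changed to all tested members after its result was seen; the splits were chosen before. A candidate explanation for the lower oocyte genes is fewer oocytes per ovary, with every oocyte gene falling by one factor. Of the 27 tested members of the list, 25 (92.6%) lay within 2 SE of the list's median of -1.69 (log2), from -2.30 to -1.41. Tle6 (-0.27 ± 0.11 SE) and Gja4 (-0.25 ± 0.18 SE), picked out after their values were seen, lay 12.8 and 7.8 SE above it, which argues against one factor for every gene of the list. Over the 24 called members alone all 24 lay within 2 SE of their median, but the calls themselves leave out small falls. One factor stays open for the other 25 genes, with SEs of up to 0.59. Expression of Tle6 and Gja4 in other ovarian cells was not tested, and oocytes were not counted here. These 2 genes thus do not argue against fewer oocytes as such.

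Other splits of the 12 libraries of each comparison were fitted, 100 of 462 drawn with the real one among them. For age the real split gave 1912 calls and the highest other 41; for Samul-tang 176 and 26; for treated against young 3795 and 426. Of the 100 drawn, only 1, the real one, gave as many calls in each case, so chance division can be excluded at that number of draws; the splits not drawn were not fitted. This does not separate treatment from depth, composition or a batch of preparation or sequencing that may go with it.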
